A study of Arabidopsis thaliana with 8 samples.

How the data were processed

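ATAC-seq was performed by the authors on nuclei from shoots (about 200 mg) of seedlings grown on plates for 7 to 9 days at 25 °C with 16 h light and 8 h dark, per the labels' protocols. Nuclei were tagmented for 30 min at 37 °C, and libraries were sequenced as paired-end reads of 150 bp. The submitters' processing notes name Trimmomatic 0.39, BWA 0.7.17, Picard, MACS2 2.2.9.1 and the TAIR10 build, without the role or order of each. Whether reads were shifted for the Tn5 insertion offset, which mapping quality was required and how organelle reads were treated are not given in the sources used here. The deposited files are 8 peak lists, 1 per library, with peaks called in each library separately. Per the file headers and format, the fold column is the authors' fold enrichment at the summit, a ratio of pileup to local background. The deposited p and q columns are on the −log10 scale, and the deposited score column is an integer made from the q value. All deposited peaks pass q of 0.05. The fold and score of a peak are the authors' own and were used only to rank, filter or describe peaks within a list. Reads were mapped to the Col-0 reference while the plants carry Ler and Cvi alleles, so a sequence difference from the reference can remove or weaken a peak.

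Groups were taken from the labels: line (149 or 50), generation (3 or 10) and lineage (1 or 2). The names of the deposited lists carry generation numbers that differ by 1 from the labels, and the labels were followed. Libraries of the same line and lineage share descent, which pairs generation 3 with generation 10. The labels also number sublineages: in 3 of the 4 lineages the generation 3 library is of sublineage 1 and the generation 10 library of sublineage 2, and in RIL149 lineage 2 both are of sublineage 1. A generation 10 library therefore need not descend from the plants sampled at generation 3, and a change per lineage includes any difference between sublineages. Samples with the same number in different lines share only the number. The pairing left no trace in the peak sets: the Jaccard index between generations was 63.1% for the same and 63.3% for the other lineage in RIL149, and 69.1% and 69.8% in RIL50. The correlation of deviations from the group means was 0.0274 in RIL149 and 0.00479 in RIL50. The labels do not say whether libraries came from single plants or pools, so p-values measure the spread between these libraries.

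Peaks on the 5 nuclear chromosomes were used. Overlapping peaks of the 8 lists (at least 1 bp) were merged into 24101 regions, and a region was present in a library that had a peak overlapping it. A region was line-specific or generation-specific when present in 4 of 4 libraries of one side and 0 of 4 of the other. Library summaries and gene list counts were compared with two-sided exact permutation tests over 70 arrangements, whose smallest p is 0.0286. Counts of specific regions and Jaccard differences were compared over the 35 splits of the libraries into 4 and 4, with a smallest share of 0.0286. Clustering along chromosomes was tested on regions held by at least 4 libraries with 10000 permutations of the marks within chromosomes, one-sided. Benjamini-Hochberg adjustment was applied over the 4 measures, the 12 lists, the 4 annotation classes and the 11 families. On simulated data with 200 planted line-specific regions among 24101, all 200 were recovered, which the definition of a specific region ensures, and 228 were called in all. The same simulation without planted regions gave 28. The lists hold no read counts. The background pileup per library was recovered from the fold and p columns by solving the Poisson relation used by MACS2, and on 2000 simulated peaks 100% were recovered. The simulated peaks were made with the same relation, so this checks the solving step only. Their backgrounds were lower than those recovered on the chloroplast. Depth limits each list: the share of peaks with a fold under 2 ranged from 0.796% to 4.84%, and the lowest fold that was listed ranged from 1.17 to 1.36.

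Genes came from a RefSeq table of assembly TAIR10.1, which differs in name from the build of the files, and none of its coordinates is printed. A position check was made in bins of 5 Mb: in 23 of 23 checked bins the overlap of peaks with gene ends was highest within 250 bp of no offset. The bin that starts at 10000001 was not among them on chromosomes 3 and 5. The table used here has no strand, exons, descriptions or class of transposable elements. The planned promoter windows were therefore replaced by windows at both gene ends, 1000 bp outside to 200 bp inside. Families were matched on symbols, synonyms and biotypes, and the transposable element family was not run. All 149 genes of the 12 lists matched by identifier. Gene-poor windows are the 40 windows of 500 kb (of 240) with fewer protein-coding genes than 50% of the median of 130.5. Named genes were chosen by a rule fixed before the data were examined: specific regions were ranked by the mean within-library percentile of the fold, and the 12 highest per line and 5 highest per generation that overlapped the end window of a protein-coding gene with a symbol were named, along with all CG maintenance genes and all list members specific to a group. Only 2 regions qualified for generation 3. One item chosen by this rule is not reported here.

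The gene lists, the tests of the main comparisons and the alternatives were fixed before the data were examined, except a filter on a fold of at least 2, which was chosen after seeing the data. The tests of distance between line-specific regions and those of the closing section that are named there were also chosen after seeing the data. The alternatives were a −log10 q of at least 5, equal numbers of peaks (the 13186 strongest of each list), windows of 201 bp around summits, coverage of at least 50% of a region, organelle peaks included, gene-end windows of 500 bp, gene bodies included, the lineage number as a block, and leaving out each library. Scripts ran under Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.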

Results

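Accessible chromatin was profiled by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA, in shoots of 7 to 9 day old Arabidopsis thaliana seedlings. The plants came from 2 recombinant inbred lines, RIL149 and RIL50, which are inbred mosaics of the accessions Landsberg erecta (Ler) and Cape Verde Islands (Cvi). The series text describes the lines as contrasting in the rate at which CG methylation changes spontaneously, without stating which rate is higher. Each line was propagated as separate lineages, and 2 lineages per line are represented by a library at generation 3 and another at generation 10, which gave 8 libraries, 4 per line and 4 per generation. Each library is represented by its own list of MACS2 peaks on the TAIR10 build, and the comparisons concern the 5 nuclear chromosomes. The lists hold no read totals. The genome-wide background pileup recovered from the peak statistics, a measure of depth, was 11.8 and 12.5 in RIL149 at generation 3 (lineages 1 and 2), 13.9 and 20.6 in RIL149 at generation 10, 8.71 and 25.3 in RIL50 at generation 3, and 20.5 and 8.88 in RIL50 at generation 10. The lists hold organelle peaks, so this pileup can include organelle reads and is not a measure of nuclear depth alone. By this measure depth differed within each line, and the absence of a listed peak means that none was detectable at that library's depth.

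The amount of accessible chromatin detected was similar in the lines and in the generations, relative to the spread between libraries. RIL149 libraries held 17850 ± 3594 nuclear peaks (SD, n = 4) and RIL50 libraries 18372 ± 995 (SD, n = 4; two-sided exact permutation test, p = 0.83). Peaks covered 6.28 ± 1.48 Mb in RIL149 and 6.81 ± 0.851 Mb in RIL50 (SD, n = 4 each; exact permutation p = 0.686). Generation 10 libraries held 19232.5 ± 1892 peaks and generation 3 libraries 16989.5 ± 2675 (SD, n = 4 each; exact permutation p = 0.229). Median peak width and median fold enrichment did not pass the test in either comparison, with a lowest exact permutation p of 0.257. One library weighed heavily on the line difference: RIL149 generation 3 lineage 2 had 13186 peaks, the fewest of the 8, and without it the mean of RIL149 was 1033 peaks above that of RIL50. From generation 3 to 10 the peak number went from 17132 to 19542 in RIL149 lineage 1 and from 13186 to 21540 in RIL149 lineage 2, while it went from 19193 to 18896 in RIL50 lineage 1 and from 18447 to 16952 in RIL50 lineage 2.

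**Figure D1:**
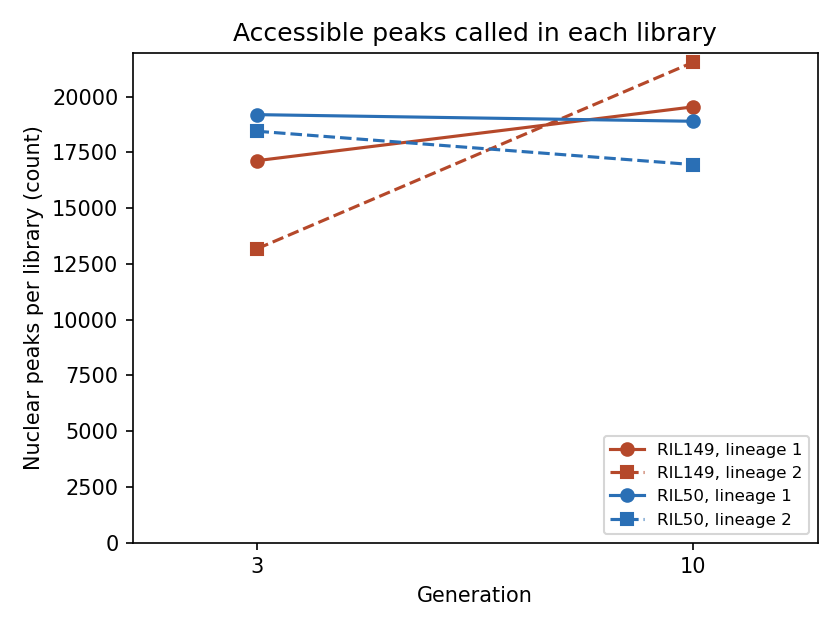
Nuclear peaks called per library (vertical axis, count) at generations 3 and 10 (horizontal axis), with a line joining the libraries of each lineage and no error bars because each point is 1 library. The RIL149 lineages end at 19542 and 21540 peaks, and the RIL50 lineages at 18896 and 16952.

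Regions open in every library were the most frequent kind. Merging the 8 lists gave 24101 regions, of which 10916 (45.3%) held a peak in all 8 libraries, 2925 (12.1%) in 1 library and the rest in 2 to 7. Of 27444 protein-coding genes, 19760 had a peak near a gene end in at least 1 library and 12025 in all 8. The shared genes included those that green shoot tissue uses. Peaks lay at the ends of 16 of 19 photosynthesis genes in all 8 libraries, among them LHCB1.3, LHCA1 and RBCS1A, which encode light-harvesting proteins and the small subunit of Rubisco. The same held for 18 of 19 genes of the circadian clock and light signalling, including CCA1, TOC1, GI and HY5, and for 9 of 10 housekeeping genes, including ACT2 and UBQ10. Of 10 root identity genes, only CASP1 had a peak in all 8 libraries, and PLT1, PLT2, RHD6 and BRN2 had none in any. Between these, EXPA7 had a peak in 6 libraries, WOX5 in 5, COBL9 in 4, BRN1 in 3 and SMB in 1. Of the 6 genes of the shoot meristem and stomatal lineage, SPCH and MUTE had peaks in all 8 libraries, STM had a peak in 1, WUS in 3, FAMA in 1, and CLV3 in 0.

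The libraries resembled their own line slightly more than the other line. The Jaccard index of covered bases, the shared length over the joint length, averaged 67.7 ± 7.18% over 12 pairs within a line and 64.7 ± 5.94% over 16 pairs between lines (SD over pairs, which share libraries). This difference of 2.95 percentage points was the highest of the 35 splits of the libraries into 4 and 4 (share 0.0286, the smallest the design allows; the next split gave 2.70). The separation was not firm: 7 of the 8 sets with 1 library left out lost it, with differences of 1.95 to 4.23 points, and peaks with a −log10 q of at least 5 gave 2.90 points (share 0.0571). Libraries of one generation were 0.709 points more similar than libraries of different generations, and 11 of the 35 splits gave a difference as large.

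**Figure D2:**
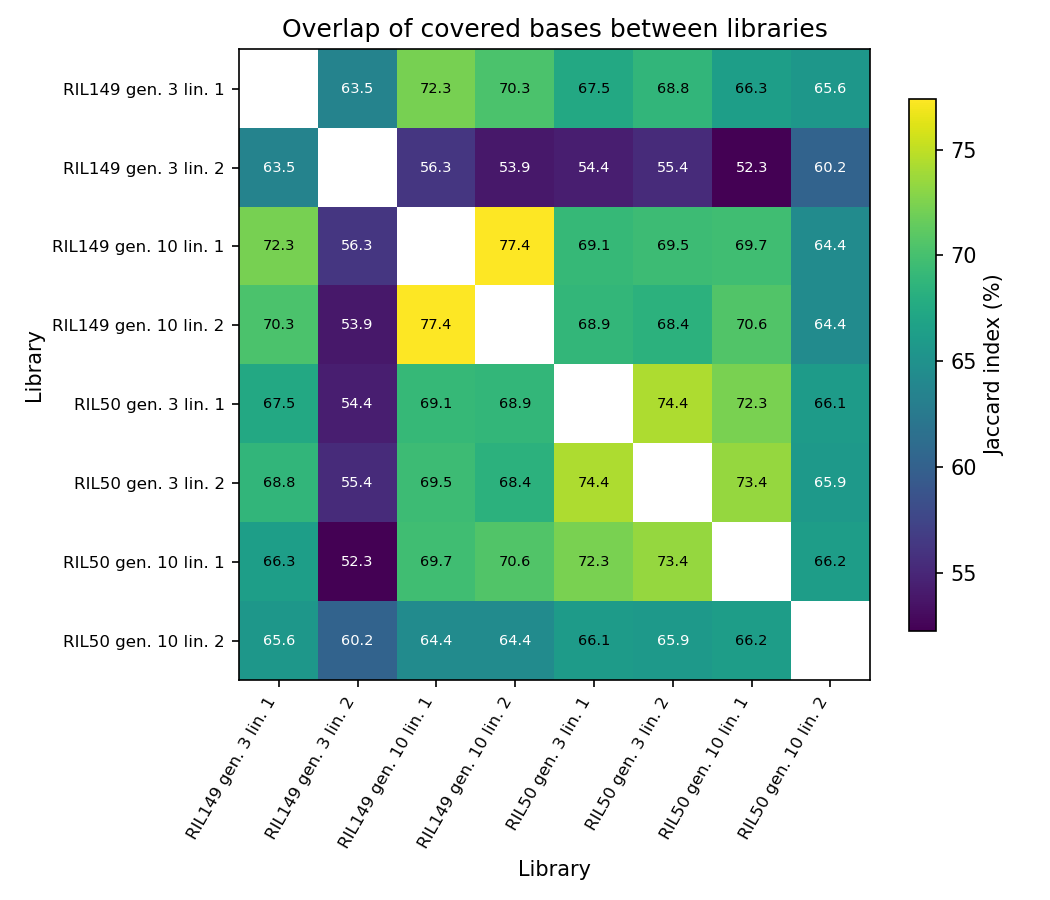
Jaccard index (percent, colour and number) of the bases covered by peaks for each pair of libraries. RIL149 generation 3 lineage 2 shares least with the other libraries, down to 52.3%, and the pair of RIL149 generation 10 libraries shares most, at 77.4%.

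The clearest differences between the lines were regions open in all libraries of one line and listed in none of the other. There were 383 such line-specific regions (1.59% of all), 170 open only in RIL149 and 213 open only in RIL50. Among the regions only in RIL149, the strongest next to genes with a symbol lay by ARO4, an armadillo repeat protein (chromosome 3, 9768618 to 9769308; fold enrichment 10.8 ± 2.19, SD, n = 4), by the Rab GTPase gene RABA5a (chromosome 5, 19280087 to 19280404; fold 10.1 ± 2.66), by ATOZI1 (chromosome 4, 360448 to 360703) and by the zinc-finger gene ZAT11 (chromosome 2, 15705877 to 15706298). The others in this direction were LBD26, a LOB-domain gene, NAPRT2, QQS, DES1, SDH3-1, RLP42, BBX18 and PHT1;9. QQS is an orphan gene that influences starch content and whose methylation varies between wild accessions. Its region (chromosome 3, 12349511 to 12349859) had its middle inside the gene and a fold of 8.91 ± 2.61 (SD, n = 4). RLP42 encodes a receptor-like protein of the immune system, DES1 a cysteine desulfhydrase, SDH3-1 a subunit of succinate dehydrogenase, and PHT1;9 a phosphate transporter.

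Among the regions only in RIL50, the strongest next to genes with a symbol lay by EMB1075, which encodes a serine decarboxylase (chromosome 1, 16489065 to 16489277; fold 20.0 ± 3.61, SD, n = 4), by the beta-glucosidase gene BGLU9 (chromosome 4, 13860513 to 13861218; fold 15.7 ± 3.00), by the glycine-rich protein gene GRP3S (chromosome 2, 1968287 to 1968565; fold 15.4 ± 3.07) and by ACS1, of the ACC synthase family of ethylene synthesis (chromosome 3, 22766802 to 22767324; fold 11.7 ± 1.25). The others were WIN2, PEX10, RRA1, RPP5, PRP40B, CF9 and EMB2758. PEX10 is a peroxisome biogenesis factor and RRA1 an arabinosyltransferase of the cell wall. RPP5 encodes a nucleotide-binding leucine-rich repeat (NLR) immune receptor. Its region lay at chromosome 4, 9544108 to 9544774. Other peaks at the ends of RPP5 were present in 3 of the 4 RIL149 libraries. NLR genes have close paralogs, so read placement there is uncertain. All of these named regions, in both directions, stayed line-specific with stricter q values, with equal numbers of peaks per library and with a fold of at least 2. At the level of whole genes, 72 protein-coding genes had end peaks in every RIL149 library and no RIL50 library, and 119 the reverse. The split by line gave the most side-specific regions of the 35 splits (share 0.0286). A single region cannot go below an exact permutation p of 0.0286, which is 1 after Benjamini-Hochberg adjustment, so 0 regions were called one by one. Without RIL149 generation 3 lineage 2, the count was 607, of which 393 were only in RIL149. Without RIL149 generation 10 lineage 2 or RIL50 generation 10 lineage 2, 343 and 345 regions were only in RIL50. Leaving out a library relaxes the rule for a specific region, so such counts cannot fall.

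**Figure D3:**
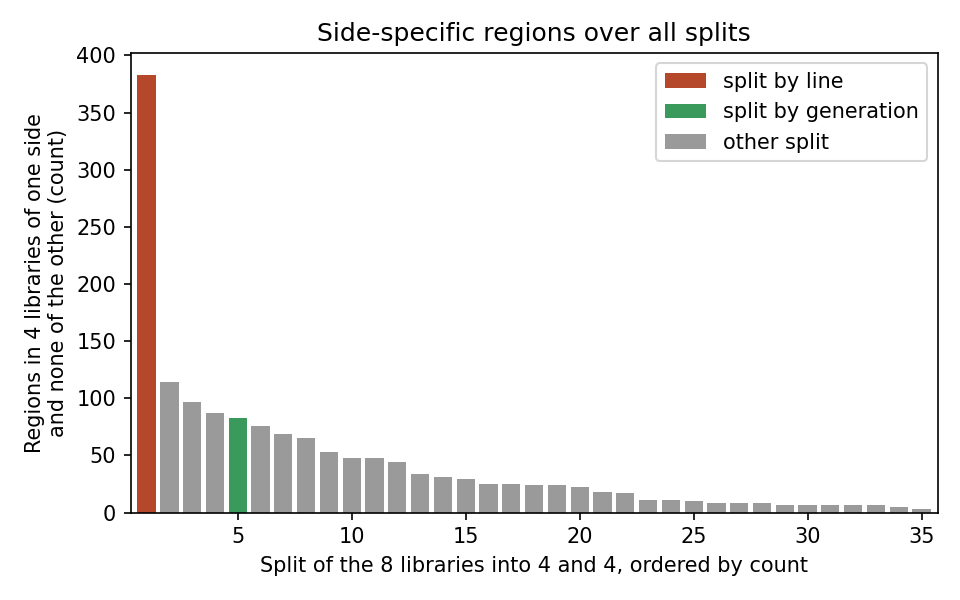
Number of regions (vertical axis) open in all 4 libraries of one side and none of the other for each of the 35 splits of the 8 libraries, ordered by count (horizontal axis). The split by line gives 383 regions, the next split 114, and the split by generation 83.

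Line-specific regions were unevenly placed along the chromosomes. Of the 17827 regions held by at least 4 libraries, 3.25% were line-specific on chromosome 3, 2.52% on chromosome 4, 1.91% on chromosome 2, 1.83% on chromosome 1 and 1.49% on chromosome 5. On chromosome 4, 19 were only in RIL149 and 50 only in RIL50, while the counts were 38 and 47 on chromosome 1, 26 and 29 on chromosome 2, 59 and 54 on chromosome 3, and 28 and 33 on chromosome 5. The difference in balance between chromosomes was not tested. The window of chromosome 4 from 11500001 to 12000000 held the most, with 9 line-specific of 95 regions, and the window of chromosome 3 from 11000001 to 11500000 held 8 of 31. Long stretches held none. The longest in regions ran from 23500001 to 27000000 on chromosome 5, where 809 regions contained 0 line-specific regions. An even spread over all chromosomes would give 17.4. Another ran from 3000001 to 6000000 on the same chromosome, with 607 regions and 13 for the same spread. The first 2500000 bp of chromosome 3 held 511 regions and 0 line-specific ones. Chromosome 5 had the lowest share, so its own share would give fewer in both of its stretches. Along the chromosomes, 13.8% of line-specific regions were followed directly by another, against 2.29% when the marks were permuted within chromosomes (permutation test with 10000 permutations, one-sided p = 0.0001, the smallest they can give). Within 50 kb of a line-specific region, another was found for 47.8%, against 33.9% with permuted marks (permutation p = 0.0001). Much of this was very local: with line-specific regions less than 10 kb apart counted as 1, 4.18% were followed directly by another, against 1.96% with permuted marks (permutation p = 0.0069). Of the 48 consecutive pairs less than 10 kb apart, 38 were open in the same line (79.2%, against 52.2% with permuted directions; permutation p = 0.0004), and of the 330 pairs farther apart 165 were (50.0%; permutation p = 0.712).

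**Figure D4:**
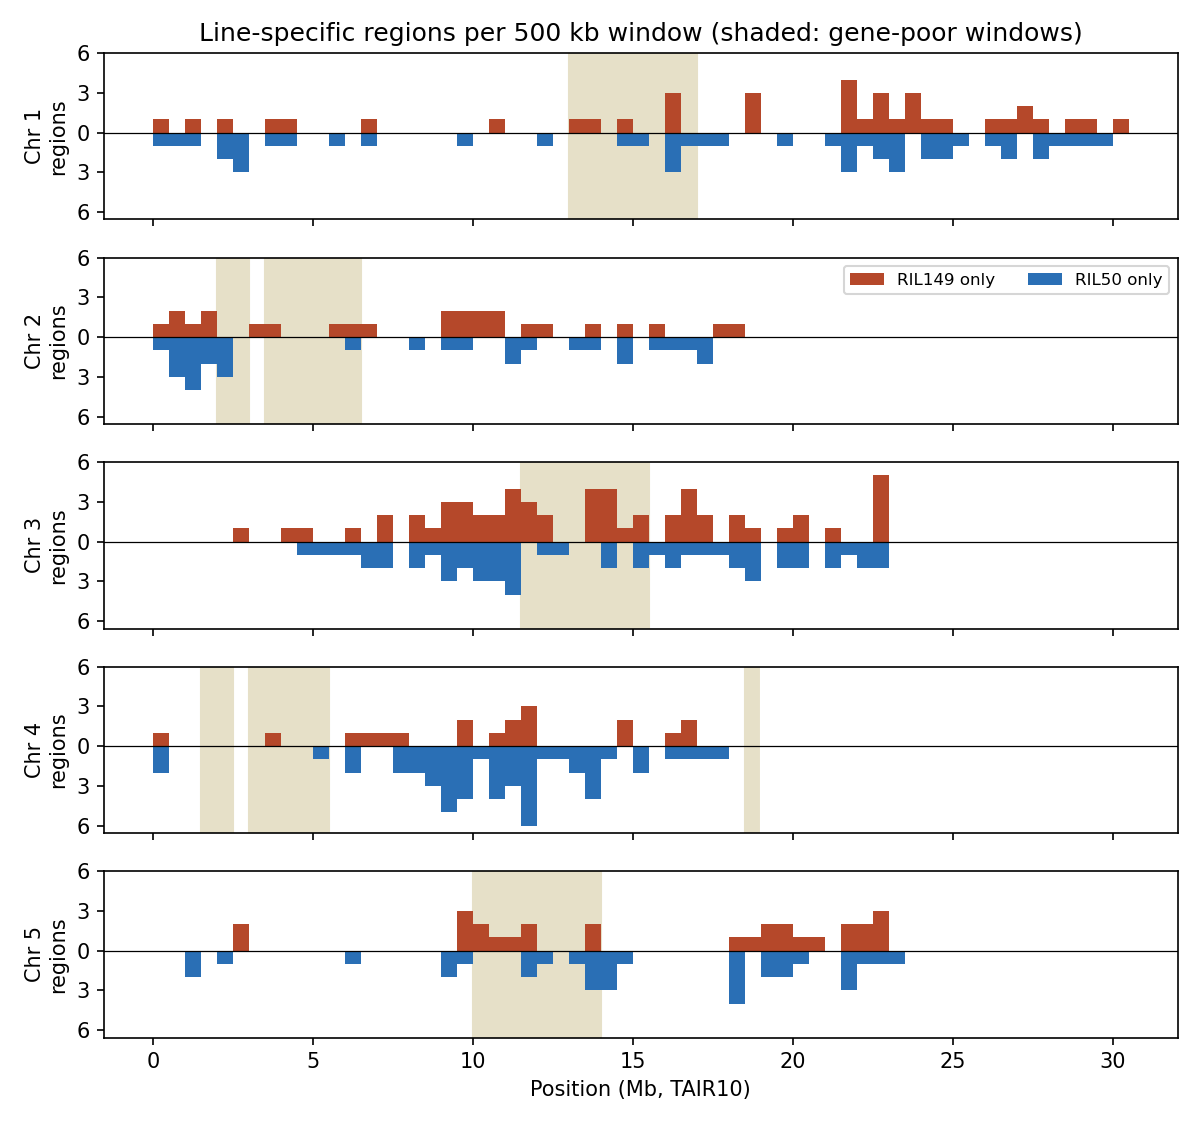
Line-specific regions per 500 kb window (count) along the 5 chromosomes (position in Mb, TAIR10), with regions only in RIL149 above the axis and regions only in RIL50 below it; shaded windows are gene-poor. Chromosome 4 holds 19 regions only in RIL149 and 50 only in RIL50, and 86 of the 239 windows with regions hold none, as in the last part of chromosome 5.

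Line-specific regions lay away from genes more often than other regions of the same prevalence. They were compared with the 1132 regions held by 4 libraries in another combination. Of the line-specific regions, 29.0% lay outside protein-coding genes and their ends, against 14.8% (odds ratio 2.34, Fisher's exact test, adjusted p = 6.0e-09). Gene-poor windows held 15.1% against 3.89% (odds ratio 4.41, Fisher's exact test, adjusted p = 1.3e-11). Gene ends were touched by 64.8% against 78.3% (odds ratio 0.510, Fisher's exact test, adjusted p = 3.8e-07). Among genes and loci next to these regions, loci labelled as pseudogenes were the 1 family of 11 that passed the test. They made up 49 of 488 loci against 43 of 1545 (odds ratio 3.90, Fisher's exact test, adjusted p = 7.8e-09). The gene table has 4843 such loci and no class for transposable element genes, so whether the label covers these is not known. This family was not tested apart from gene-poor windows. Receptor-like kinases and proteins made up 8 of 488 against 9 of 1545 (odds ratio 2.84, Fisher's exact test, adjusted p = 0.149), and non-coding RNA genes 75 of 488 against 176 of 1545 (odds ratio 1.41, adjusted p = 0.122, Fisher's exact test). The receptor-like family passed with a −log10 q of at least 5 (Fisher's exact test, adjusted p = 0.0344), and the non-coding RNA genes with windows of 500 bp (adjusted p = 0.0223). Neighbouring regions are not independent, so these p-values are too small by an unknown amount.

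The lines are described as contrasting in the rate of spontaneous CG methylation change. Genes that maintain CG methylation did not differ between the lines in the presence of peaks at gene ends. MET1, the maintenance DNA methyltransferase, and DDM1, a chromatin remodeller, had a peak at a gene end in all 8 libraries. VIM1, VIM2, VIM3, VIM4 and VIM5, whose products bind hemimethylated DNA, had none in any library. The nearest listed peak lay 3034 to 3091 bp from VIM3 across the libraries and at least 5741 bp from VIM2. The nearest to VIM4 lay 1372 and 1373 bp away in the lineage 1 libraries of RIL50, at generations 3 and 10, and at least 11761 bp away in all 4 RIL149 libraries and at least 11769 bp away in the other RIL50 libraries. VIM2 and VIM4 are close copies of each other, and reads from such copies can be hard to place. Of 22 genes of RNA-directed DNA methylation, 6 had peaks in all 8 libraries and 6 in none. CLSY4 had a peak in 3 RIL149 libraries and 0 RIL50 libraries, and DRD1 in 2 and 4. The count per library was 13 ± 3.56 in RIL149 and 13.5 ± 1.29 in RIL50 (SD, n = 4 each; exact permutation p = 0.943). Among the 6 genes of non-CG and H3K9 methylation, SUVH4 had a peak in all 8 libraries, SUVH5 in 2 of RIL149 and 4 of RIL50, and IBM1 in 2 of RIL149 and 0 of RIL50. With the gene body included, IBM1 had peaks in 2 libraries of each line. Of the 5 demethylation genes, ROS1 and DME had peaks in all 8, and DML2 in 1 RIL149 library and 3 RIL50 libraries. Of 11 genes of histone variants and chromatin assembly, 6 had peaks in all 8, while the linker histone gene H1.2 had one in 2 RIL149 libraries and 0 RIL50 libraries, and the histone variant gene HTA9 in 2 and 4. For DRD1, SUVH5, IBM1, H1.2 and HTA9, the 2 RIL149 libraries with an end peak were those of generation 10. Of the 10 genes of flowering, dormancy and known Ler or Cvi variation, 7 had peaks in all 8 libraries, including CRY2, ERECTA and FLC.

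Immune receptor genes held the 2 members of the fixed lists that were specific to a line. RPP4 and RPP7, NLR receptors for downy mildew, had end peaks in 4 of 4 RIL50 libraries and 0 of 4 RIL149 libraries. With the gene body included, RPP7 had peaks in all 8 libraries and RPP4 remained specific. Read placement in NLR genes is uncertain, as at RPP5. Of all 27444 protein-coding genes, 72 were specific to RIL149 and 119 to RIL50. The 2 of 149 list genes were not tested against that share. Among the families, NLR genes did not pass, with 2 of 488 loci against 0 of 1545 (Fisher's exact test, adjusted p = 0.158). Over the 24 disease resistance genes, 16.0 ± 4.40 had an end peak per RIL149 library and 18.5 ± 1.00 per RIL50 library (SD, n = 4 each; exact permutation p = 0.343). Root identity genes gave 2.75 ± 1.5 and 4.00 ± 0.816 (SD, n = 4 each; exact permutation p = 0.314). None of the 12 lists passed the exact permutation test between lines (0 at an unadjusted p under 0.05, lowest adjusted p = 1) or between generations (0 at an unadjusted p under 0.05, lowest adjusted p = 0.629).

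The comparison of generations asked whether further selfing within lineages was accompanied by gains or losses of accessible regions. Across both lines, 79 regions were open in all 4 generation 10 libraries and none of generation 3, and 4 the reverse. The strongest regions only in generation 10 next to genes with a symbol lay by PRA1.B2, MYB54, CYP704B1, WRKY70 and MYC3. MYB54 is linked to secondary cell walls, CYP704B1 to pollen wall formation, WRKY70 to salicylic acid signalling and MYC3 to jasmonate signalling. Their folds were modest, from 4.36 ± 0.729 at PRA1.B2 (chromosome 2, 16865370 to 16865586) to 3.59 ± 0.418 at MYC3 (chromosome 5, 18976222 to 18976726; SD, n = 4 each). The regions only in generation 3 with a named gene lay by ACR8 (chromosome 1, 4229128 to 4229372; fold 2.44 ± 0.399) and BBD1 (chromosome 1, 28280958 to 28281424; fold 1.99 ± 0.295; SD, n = 4 each). Neither of these regions remained specific with a −log10 q of at least 5 or with a fold of at least 2. This total of 83 was reached by 5 of the 35 splits (share 0.143), so it did not pass the test. With equal numbers of peaks per library the direction turned, to 22 regions only in generation 10 and 43 only in generation 3, and MYB54 and CYP704B1 were the 2 named genes whose regions remained specific. Leaving out 1 library, which relaxes the rule so that the total cannot fall, gave between 100 and 218. The highest count came without RIL50 generation 10 lineage 2. The disease resistance genes with an end peak numbered 19.25 ± 1.26 per generation 10 library and 15.25 ± 3.50 per generation 3 library (SD, n = 4 each; exact permutation p = 0.114).

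Within RIL149, 2276 regions were open in both generation 10 libraries and neither generation 3 library, and 11 the reverse. Dividing the same 4 libraries by lineage gave 249 regions in all, and the crossed division 436. Within RIL50, 277 regions were only in generation 10 and 587 only in generation 3, against 667 for the division by lineage and 594 for the crossed one. With 2 libraries per side no exact test can go below p = 0.333, so these counts were not tested. With equal numbers of peaks per library, 482 regions of RIL149 were only in generation 10 and 356 only in generation 3. In RIL50 that setting gave 308 and 351.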

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

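The tests of depth against the split by line, of the longest run, of depth and organelle DNA against the generation change, and of both relations across the 8 libraries were chosen only after the result was seen, as was the filter on a fold of at least 2. The peak number changed in opposite directions in the lines: from generation 3 to 10 the mean change was 5382 in RIL149 (2410 and 8354 in the 2 lineages), and -896 in RIL50 (-297 and -1495). Both lineages of each line moved the same way, and the difference between the lines was not tested, since 2 lineages against 2 cannot go below an exact permutation p of 0.333. A detection limit set by depth remains open: all 4 lineages kept their direction with a fold of at least 2, but this filter removed under 5% of each list. With a −log10 q of at least 5 the change in RIL50 lineage 1 was +213. Of the 4 changes with a fold of at least 2, 3 were smaller than the SD between libraries of the line (3594 in RIL149, 995 in RIL50). The SDs used here span both generations, so they include the changes they are set against. Sequencing depth cannot be told apart either, because the background pileup moved with the peak number in 3 lineages of 4. In the exception, RIL50 lineage 1, the pileup rose from 8.71 to 20.5 while the peak number changed by -297. That peak change was smaller than the SD of 995, so the direction in this lineage decides little. Organelle DNA also stays open: its measure, the local chloroplast background over the genome-wide background, moved against the peak number in 3 lineages of 4, and in the exception, RIL50 lineage 2, it went from 335 to 328, a change within the SD of 43.9 between RIL50 libraries, while the peak number changed by -1495. A difference between the lines over generations, or between the sublineages sampled, stays open as an untested biological explanation.

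Peak number also differed widely between libraries of one line and generation, with 17132 and 13186 in RIL149 at generation 3. Across the 8 libraries, it was lower where the chloroplast ratio was higher (Pearson's r = -0.776, exact permutation p = 0.0400, adjusted over 2 relations p = 0.0800; Spearman's rho = -0.714, exact permutation p = 0.0576). The library with the fewest peaks had the highest ratio, 419, and RIL50 generation 3 lineage 1, with 19193 peaks, the lowest, 243. Without the 2 libraries farthest from the median ratio r was -0.412 (exact permutation p = 0.432), so the relation rests on those libraries. With background pileup, r was 0.39 (exact permutation p = 0.356, adjusted p = 0.356; rho = 0.333, p = 0.428), and 0.189 without the 2 farthest (exact permutation p = 0.675). Neither organelle DNA nor sequencing depth can be told apart from differences between the plants with 8 libraries. The 2 measures are also not separate, since the background pileup can include organelle reads and is the divisor of the chloroplast ratio.

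The count of line-specific regions was set against technical explanations. Of the 35 splits, 1, the real one, gave 383 regions, and the highest other split gave 114. The share of the real split, 0.0286, is the smallest the design allows, so the splits argue against chance but cannot exclude it. They also treat the libraries as exchangeable, although those of one line and lineage share descent. With equal numbers of peaks per library the count was 412, which argues against different peak numbers as the cause. The split into the 4 libraries with higher and the 4 with lower background pileup gave 76 regions. This argues against depth as measured by that pileup, which can include organelle reads. The filter on a fold of at least 2 left 377 regions but removed under 5% of each list, so by itself it does not decide on a detection limit. Sequence differences of Ler or Cvi from the reference, which change how reads map, were not tested and stay open beside a difference in chromatin.

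For regions specific to a generation chance cannot be excluded, since 5 of the 35 splits gave at least as many as the 83 regions of the real split, and the highest other split gave 383, the split by line.

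RIL149 generation 3 lineage 2 had 72 chloroplast peaks, against 77, 78 and 78 in the other RIL149 libraries. The value of 72 was the 1 outlying value among 32 sets of 4 libraries and measures, where chance gives about 1.6. The lists also held peaks on the organelle genomes, which the comparisons did not use: 285 in the library with the fewest and 320 in the library with the most.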

How the results depend on the processing

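The filter on a fold of at least 2 was chosen after seeing the data; the other settings were not. Of 271 alternatives, 220 kept direction and side of the threshold (or stayed within the limits set for counts), and the cause of the changes below was not tested. Leaving out 1 library each gave line differences of -1752 to 1033 peaks, -0.955 to 0.145 Mb and -0.224 to 0.149 in median fold, and generation differences of -4.50 to 10.4 bp in median width. It gave Jaccard differences of 1.95 to 4.23 points by line and -0.863 to 2.19 by generation, 412 to 607 line-specific regions (172 to 393 only in RIL149, 214 to 345 only in RIL50) and 100 to 218 generation-specific regions (83 to 214 only in generation 10, 4 to 30 only in generation 3). The counts of specific regions cannot fall when a library is left out, since the rule is then relaxed. A −log10 q of at least 5 gave a Jaccard difference by line of 2.90 points, 1 region only in generation 3, 6 regions only in generation 3 within RIL149, and 2 families called. Equal numbers of peaks gave 22 regions only in generation 10 and 43 only in generation 3, and within lines 482 (RIL149, generation 10), 356 (RIL149, generation 3) and 351 (RIL50, generation 3). A fold of at least 2 gave 1 region only in generation 3 and 17 only in generation 3 within RIL149. Windows of 500 bp gave 2 families called and an odds ratio of 1.07 for gene bodies, and including gene bodies left 1 list gene specific to a line. With the lineage number as a replicate block, the Jaccard difference by line of 2.95 points and the 383 line-specific regions had a share of 0.125, the smallest that its 8 splits allow, so the block cannot pass the threshold and says nothing about stability. It changed no other call. Lineage numbers pair libraries by descent only within a line. Depth limits all counts of absent peaks, since background pileup ranged from 8.71 to 25.3.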

Other observations

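The tests of the longest run, of neighbours less than 10 kb apart and of the neighbour share with these counted as 1 were chosen only after the result was seen. The longest run with nearby regions counted as 1 and the test outside gene-poor windows were set before their own results but after the clustering had been seen. Most of the highest peaks of each list lay in gene-poor windows, and the top-ranked peak differed by line. Of the 20 peaks with the highest −log10 q, 14 to 19 per library were in gene-poor windows, which held 3.00% to 3.48% of all peaks. The top peak of all 4 RIL149 libraries was on chromosome 4 near 3953404 to 3953710 (fold 19.1 to 20.3). That of all 4 RIL50 libraries was on chromosome 3 from about 13590284 to 13590890 (fold 12.4 to 13.6). In the lists of RIL50 generation 3 lineage 2 and generation 10 lineage 1 it extended to 13591690 and 13591692. Neither top peak lay in a line-specific region, so at least 1 library of the other line had a peak in the same merged region. How many libraries of the other line did so was not examined.

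RIL149 and RIL50 are mosaics of the same parents, so a hypothesis is that line-specific regions fall where the lines carry different parental alleles and are missing where they carry the same one. The longest run of regions without a line-specific one was 834 regions, against a mean of 335 with permuted marks, whose middle 95% ended at 501 (permutation test, one-sided p = 0.0002), and 86 windows of 500 kb held none, against 68.1 (middle 95% 59 to 77, permutation p = 0.0004). Counting line-specific regions less than 10 kb apart as 1 left 335 marks and a longest run of 834 (permuted mean 361, middle 95% up to 538, permutation p = 0.0003). Removing marks cannot shorten the run, so only the permuted range could move. The run stayed above that range, so a count of marks raised by split loci does not by itself account for it. The empty windows were then only just outside the permuted range, 86 against 75.9 (middle 95% 67 to 85, permutation p = 0.022). Neither the longest run nor the empty windows were tested without gene-poor windows, where line-specific regions were more frequent. An uneven density along the chromosomes was therefore not separated from blocks of parental alleles.

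The share of line-specific regions followed by another, 13.8%, says less about such blocks, since it fell to 4.18% when regions less than 10 kb apart were counted as 1 (middle 95% of permutations up to 3.58%, permutation p = 0.0069), a step that removes close followers by construction. Whether these are single loci split into several regions was not decided by it. Gene-poor windows alone do not account for the share, since outside them 12.6% were followed by another (permuted mean 2.05%, middle 95% up to 3.69%, permutation p = 0.0001, the smallest the permutations can give). Close neighbours were not counted as 1 in that test, and repeats outside these windows were not tested. Repetitive sequence therefore stays open as a cause. One-sided segments of a few kb, such as deletions or sequence that maps poorly in one line, may contribute to the close neighbours, of which 79.2% of 48 pairs had the same direction (middle 95% of permutations 37.5% to 66.7%, permutation p = 0.0004). Longer one-sided segments stay open: 53.7% of all 378 neighbouring pairs had the same direction (middle 95% of permutations 46.6% to 56.3%, permutation p = 0.189), but most of these pairs lie far apart, and permuting directions within chromosomes leaves out the imbalance of chromosome 4, with 19 regions only in RIL149 and 50 only in RIL50. No marker genotypes were used here, so the parental origin of the segments was not tested, and mapping differences between alleles would follow the same segments.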
